A study of Mus musculus with 32 samples.

How the data were processed

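RNA of mouse kidney was measured by sequencing in 32 libraries, 4 in each of 8 groups given by the labels: WT (floxed Hmox1) and KO (inducible whole-body deletion) kidneys, untreated (0 h) or 6, 12 or 20 h after hemin. Per the labels' protocols, total RNA was extracted with the mirVana kit and libraries were made from polyA-selected RNA with the NEBNext Ultra II Directional kit. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20.0.422, checked with FastQC, trimmed with Trimmomatic 0.36, aligned to GRCm38 with HISAT2 2.1.0 and counted per gene with HTSeq, and DESeq2 is also named. The role of each tool beyond its usual one, the strand setting of the counting and the annotation release are not given in the sources used here. The unit of the deposited values is the raw count of reads per gene, with 1 file per library and no normalization. Reads that align to several places were not assigned to a gene, so genes with near-identical copies are undercounted, and counts of overlapping or antisense genes are uncertain because the strand setting is not known.

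Each file held 46078 gene IDs and 5 summary lines, which were left out of library sizes and tests. The summary lines took 27.6 to 35.8% of each file's total: reads in no gene 3.37 to 6.77%, in several genes 0.761 to 0.968%, aligned to several places 21.7 to 29.2% and not aligned 0.792 to 1.60%. Gene counts summed to 47269346 to 57284988 per library, and 21229 to 23451 genes had at least 1 count, so counting error is small for all but the lowest genes and the spread between libraries sets the precision. A gene with 0 counts in every library of a group was given a floor of 3 counts per library, and its fold is printed as a lower bound, which covers counting error only. Symbols and positions came from GENCODE release M21 (GRCm38), in which 45229 IDs had a symbol and 849 did not. All counts were 0 for 15506 IDs.

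Genes were kept with edgeR's filterByExpr (minimum count 10), which left 18162. Counts were scaled with TMM factors, and edgeR's quasi-likelihood test (robust, prior count 0.125) was fitted over all 32 libraries with 1 mean per group, so that all groups share the estimate of spread. The 13 comparisons were KO against WT at each time, each time against 0 h within each label, and the interaction of label and hemin at each time. P-values were adjusted by the Benjamini-Hochberg (BH) method within a comparison, and a gene passed at an adjusted p under 0.05. Standard errors were derived from the log2 fold change and its F statistic. Hmox1 was also compared per library by a two-sided exact permutation test of log2(CPM + 0.5).

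Of 54 gene lists, 38 were of pathways and 16 of cell types. Each was tested with camera, limma's test of whether a list's signed z values lie apart from those of the other genes, with a preset correlation of 0.01 between genes and BH adjustment over the lists. It was run again with the correlation between members estimated from the libraries. Hmox1 was left out of every list, and counts of members are given over all genes and adjusted over the list alone. A list of at least 3 tested members was tested, and the report describes those bearing on metabolism, stress and cell types.

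The genes named were chosen by a rule: Hmox1 always; for KO against WT also a set of 16 genes of iron handling, metabolism and tubule state; the 5 highest and 5 lowest log2 fold changes past the threshold with at least 5 CPM in 1 group, no overlap between the libraries of the groups (not asked of the interaction) and no predicted gene; and up to 4 members of each described list with the largest change, or its highest expressed members where none passed. Changes called highest or lowest are so under this rule. Some genes that the rule picks are not reported here. The groups, comparisons, lists, naming rule and first set of alternatives were fixed before the data were examined.

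Alternatives were RLE and upper-quartile factors, no filter, a minimum count of 50, DESeq2, a fit on only the compared groups, the replicate number as a block, leaving out each library in turn, pseudocounts of 0.1 and 1 CPM for Hmox1, and the estimated correlation. Alternatives chosen after seeing the data were a term for the sex of each library, read from Xist and the Y-linked genes, a term for its summed adipocyte marker level, scaling by library size alone, and the male or female libraries alone. Genes matched on transcript length, GC content and mean expression (50 nearest) were compared with 1000 bootstrap draws of genes, not libraries, in 83.9% of tested genes.

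The test was run on simulated counts of 17836 genes for KO against WT at 12 h, with genes changed by known folds. It recovered 16.4% of genes changed 1.5-fold, 50.8% at 2-fold and 81.8% at 4-fold, and called 8 of 17566 unchanged genes. The shifted list was called and 0 others were, with few other genes changed and false list calls among correlated genes untested. For matching, 15236 genes with their real features were given a trend with length, and the matched difference of 72 oxidative phosphorylation genes was 0.04 with no shift and 0.54 with a shift of 0.5. Vehicle-treated controls, reads and protein were not analysed here.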

Results

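Messenger RNA of mouse kidney was sequenced from animals with a floxed Hmox1 gene, called WT-labelled here, and from animals with an inducible whole-body deletion of it by Cre-ERT2 from the Rosa26 locus, called KO-labelled. Hmox1 encodes heme oxygenase-1, the inducible enzyme that breaks heme down into biliverdin, iron and carbon monoxide, and hemin is an oxidized form of heme. Kidneys were untreated (0 h) or taken 6, 12 or 20 h after hemin, with 4 libraries in each of 8 groups. The series title names central carbon metabolism of the kidney, and its design text sets WT against KO at each time. Gene counts summed to between 47269346 and 57284988 per library (median 49918895). Of the 48 pairs of libraries within groups, 0 were identical, and their counts differed by more than sampling noise (chi-square per gene from 10.9 to 482). The labels do not state whether libraries came from separate animals, so p-values measure only the spread between these samples. Part of it may be technical, though the 5 groups that hold both sexes cannot each come from 1 animal.

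Xist, transcribed from the inactive X chromosome, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty separated the libraries into 18 male and 14 female ones, with Xist at 156 CPM (counts scaled to library size) or more in the females and 0.212 or less in the males. All 4 WT-labelled libraries at 0 h were male, and KO-labelled ones at 0 h were 3 male and 1 female. At 6 h all 4 WT-labelled libraries were female and all 4 KO-labelled ones male, so at that time neither sex was present under both labels. Both groups at 12 h and the WT-labelled group at 20 h held 2 of each sex, and the KO-labelled group at 20 h held 1 male and 3 females.

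Hmox1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589, GRCm38) did not pass the test as lower in KO-labelled than in WT-labelled kidneys at any time. In untreated kidneys it was higher in all 4 KO-labelled libraries, at 205 ± 98.6 CPM (SD, n = 4, 75.2 to 287), than in the 4 WT-labelled ones, at 31.6 ± 10.6 CPM (22.1 to 46.6). The difference of mean log2 CPM was 2.56 (two-sided exact permutation test, n = 4 per group, p = 0.0286, the smallest p these group sizes allow), and edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p was 0.0012. After hemin the groups overlapped. Hmox1 stood at 399 ± 154 against 399.8 ± 54.8 CPM at 6 h (KO-labelled against WT-labelled, two-sided exact permutation p = 0.80), at 1254 ± 108 against 1242 ± 596 at 12 h (exact p = 0.914) and at 1247 ± 663 against 1331 ± 303 at 20 h (exact p = 0.686). Relative to 0 h, Hmox1 rose in WT-labelled kidneys by 3.66 ± 0.43 (log2 fold change ± SE) at 6 h, 5.30 ± 0.46 at 12 h and 5.40 ± 0.47 at 20 h. In KO-labelled kidneys the value at 6 h was 0.96 ± 0.39 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0644, not past 0.05; 1.16 and past it without KO-labelled 0 h replicate 2, 1.15 without KO-labelled 6 h replicate 3), and Hmox1 rose by 2.61 ± 0.41 at 12 h and 2.60 ± 0.41 at 20 h. Counts were summed over the whole gene, so reads from exons outside a deleted segment or from cells without the deletion are included, and the position of the deleted segment is not given in the sources used here. The file numbers of 2 of 32 libraries, WT-labelled 0 h replicate 4 and KO-labelled 20 h replicate 1, are out of sequence, and each file was taken for the sample it is listed under. Gt(ROSA)26Sor, from the locus that carries Cre-ERT2, stood at -0.38 ± 0.21, -1.12 ± 0.22, -1.85 ± 0.22 and -1.53 ± 0.22 (KO against WT at 0, 6, 12 and 20 h), lower in every KO-labelled library after hemin and not past the threshold at 0 h. The predicted gene Gm26917 was higher in every KO-labelled library at all 4 times, at 2.39 ± 0.27, 1.10 ± 0.26, 1.04 ± 0.26 and 1.16 ± 0.26, though it did not pass at 6 h with the sex term. Both were chosen after their values were seen. Because Hmox1 counts do not follow the labels, groups are named below by their labels, and every direction between genotypes is one between labels.

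**Figure D1:**
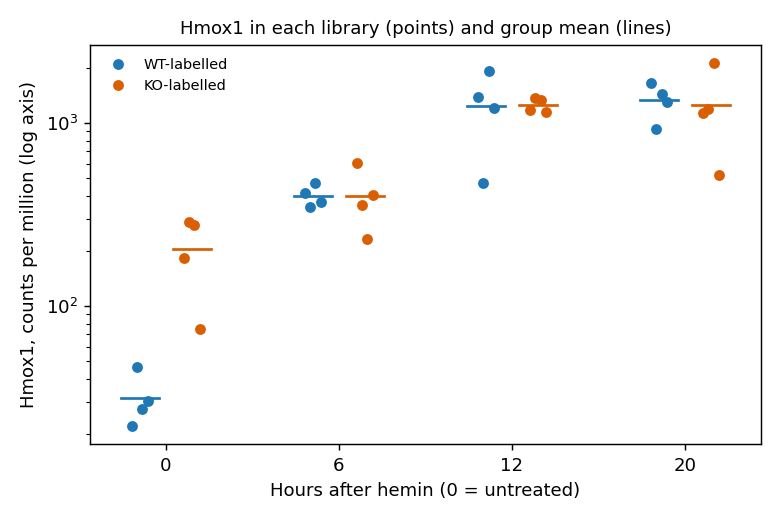
Hmox1 CPM (log axis) in each of the 32 libraries by hours after hemin, with 4 libraries per group and the group mean as a line. At 0 h the 4 KO-labelled libraries lie between 75.2 and 287, above the highest WT-labelled library at 46.6, and at 6, 12 and 20 h the groups overlap.

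The comparison of untreated kidneys asks how the genotype labels differ before hemin. Besides Hmox1, the complement component C3 was higher in KO-labelled kidneys by 4.08 ± 0.56 (log2 fold change ± SE, n = 4 per group) and Tgfb2, a growth factor of tissue fibrosis, by 4.62 ± 0.69. Kcna1, a potassium channel subunit, Adgrg2, an adhesion receptor, and Ppp1r3b, a targeting subunit of glycogen phosphatase, were higher by 4.84 ± 0.88, 3.23 ± 0.50 and 3.33 ± 0.79. Among the lowest log2 fold changes were -2.95 ± 0.53 for the mitotic kinesin Kif20b, -1.97 ± 0.49 for Tc2n, -1.71 ± 0.39 for Odc1, the first enzyme of polyamine synthesis, -1.43 ± 0.33 for acetoacetyl-CoA synthetase Aacs and -1.39 ± 0.31 for Pank1, a kinase of coenzyme A synthesis. In all, 133 of 18162 genes passed an adjusted p of 0.05, 80 higher and 53 lower in KO-labelled kidneys, and 67 and 25 of these differed at least 2-fold.

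Several lists passed camera with few or no single members passing. Nuclear genes for oxidative phosphorylation, the respiratory chain and ATP synthase, had 0 of 72 higher and 0 lower (0 and 0 adjusted over the list alone). The median log2 fold change was -0.27 (camera, adjusted p = 1.44e-11, adjusted p = 0.584 with an estimated correlation). Proximal tubule markers, genes of the reabsorbing epithelium, had 0 of 36 higher and 2 lower (2 and 6 adjusted over the list alone). The median was -0.31 (camera, adjusted p = 3.11e-04, adjusted p = 0.448 with an estimated correlation). The members that passed were Keg1 (-1.05 ± 0.24) and the phosphate transporter Slc17a1 (-0.95 ± 0.21). Adipocyte markers stood apart with a median of 6.40 (camera, adjusted p = 2.77e-11, adjusted p = 0.326 with an estimated correlation). They had 2 of 9 higher and 0 lower (9 and 0 adjusted over the list alone), among them the adrenergic receptor Adrb3 (6.62 ± 1.46) and the lipid droplet gene Cidec (5.15 ± 1.23). Their summed level ranged from 7.03 to 959.9 CPM in KO-labelled and from 0.670 to 19.0 CPM in WT-labelled libraries. Summed markers of the proximal tubule were lower in every KO-labelled than in every WT-labelled library (37418 to 49965 against 57007 to 76468 CPM). Those of mesangial cells and fibroblasts (899.5 to 1345 against 553 to 681 CPM) and podocytes (614 to 742 against 461 to 546 CPM) were higher. These and later sums use no TMM factors (means 1.186 against 1.056). Chance gives such a parting in 2.86% of the 16 cell types. Of iron genes, log2 fold changes were -0.44 ± 0.20 for the ferritin heavy chain Fth1, 0.06 ± 0.21 for the ferritin light chain Ftl1, 0.48 ± 0.27 for the iron exporter Slc40a1 and -0.14 ± 0.23 for the transferrin receptor Tfrc. Gluconeogenic genes had 0 of 28 higher and 0 lower (1 and 1 adjusted over the list alone). The median was -0.14 (camera, adjusted p = 0.0557). Pck1 stood at -0.13 ± 0.38, G6pc at -0.47 ± 0.52 and Fbp1 at -0.43 ± 0.26. With scaling by library size alone the median of all genes moved by 0.17 and the calls split into 159 higher and 30 lower, and the gluconeogenesis median was 0.03. Against genes matched on transcript length, GC content and expression level, the list median became a difference of -0.12 (95% bootstrap interval -0.16 to -0.09) for oxidative phosphorylation and -0.18 (-0.45 to 0.03) for proximal tubule markers. Such matched differences are given, with that interval, where they shrink a described list's median by over 1.5 times or turn it. With the summed adipocyte level as a term in the model 25 genes passed, and of those named above Hmox1, C3, Tgfb2, Kcna1 and Adgrg2 did. Of those that did not, Kif20b (-2.55), Tc2n (-1.86), Odc1 (-1.46), Aacs (-1.45), Pank1 (-1.17), Keg1 (-0.87) and Slc17a1 (-0.84) had log2 fold changes within 1.5 times of those given, and Ppp1r3b (1.14), Adrb3 (0.55) and Cidec (0.24) smaller ones. With sex as a term 234 passed, and Ppp1r3b did not. The count fell to 36, 30, 58 and 46 without WT-labelled 0 h replicates 1, 2, 3 and 4 in turn and 68 and 28 without KO-labelled 0 h replicates 1 and 3 in turn. Without 1 library or another Ppp1r3b, Tc2n, Odc1, Aacs, Pank1, Keg1, Slc17a1, Adrb3 and Cidec did not pass, and without KO-labelled replicate 4, the female, Ppp1r3b stood at 1.65 and Pck1 at -0.68. Gluconeogenesis passed without that library (-0.20) or WT-labelled replicate 3 (-0.15), and oxidative phosphorylation did not without WT-labelled replicate 1 (-0.02; -0.40 without replicate 4).

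At 6 h the 4 KO-labelled libraries were all male and the 4 WT-labelled all female, so each difference below is also one between the sexes. Among the largest were those of the sex chromosomes, with Xist at -11.79 ± 3.62 (log2 fold change ± SE, n = 4 per group), Eif2s3y at 12.03 ± 3.65, Ddx3y at 11.49 ± 3.51, Kdm5d at 11.04 ± 3.31 and Uty at least 407-fold higher against a group at 0. Others were those of the organic anion transporter Slco1a1 (11.04 ± 3.22), the glucuronosyltransferase Ugt1a2 (-8.40 ± 2.40), the muscle myosin Myh1 (-6.86 ± 1.75), the phosphate transporter Slc17a2 (-5.38 ± 1.03) and the growth factor Igf2 (-5.33 ± 1.39). Proximal tubule markers had 5 of 36 higher and 1 lower (16 and 2 adjusted over the list alone), among them the amino acid transporter Slc7a13 (9.03 ± 2.66), the steroid hydroxylase Cyp7b1 (6.44 ± 1.86) and Cyp2e1 (3.93 ± 0.98). The list had a median of 0.53 (camera, adjusted p = 1.76e-04, adjusted p = 0.431 with an estimated correlation). In all, 1624 genes passed, 694 higher and 930 lower. With sex as a term in the model 81 passed, 36 higher and 45 lower, and of the genes named for this time Slc17a2, Fasn and Acaca were among them.

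Cholesterol synthesis genes had 7 of 24 higher and 0 lower (11 and 0 adjusted over the list alone), with Idi1 (1.82 ± 0.41) and Insig1 (1.34 ± 0.35) among them. The list had a median of 0.57 (camera, adjusted p = 7.79e-07, adjusted p = 0.431 with an estimated correlation). Fatty acid synthesis had 4 of 18 higher and 0 lower (5 and 0 adjusted over the list alone), and both its main enzymes, fatty acid synthase Fasn (2.91 ± 0.82) and acetyl-CoA carboxylase Acaca (2.50 ± 0.69), were among them. Its median was 0.35 (camera, adjusted p = 0.0026, adjusted p = 0.431 with an estimated correlation). Adipocyte markers again moved with the groups, with 2 of 9 higher and 0 lower (9 and 0 adjusted over the list alone). Their median was 4.50 (camera, adjusted p = 5.47e-05, adjusted p = 0.448 with an estimated correlation). The lipid droplet genes Plin1 (5.25 ± 1.57) and Cidec (3.66 ± 1.13) were higher. The summed markers ranged from 27.0 to 562 CPM in KO-labelled and from 2.86 to 34.1 CPM in WT-labelled libraries. Summed proximal tubule markers were higher in every KO-labelled library (47878 to 62161 against 36652 to 39331 CPM). Those of the thick ascending limb (5586 to 5900.3 against 8533 to 11362 CPM), distal convoluted tubule (1006 to 1413 against 1588 to 1962 CPM), principal cells (662 to 806 against 992 to 1379.6 CPM), intercalated cells (319.8 to 343 against 443 to 609 CPM), neutrophils (18.7 to 27.4 against 39.8 to 59.6 CPM) and the adrenal gland were lower in every one. Gluconeogenesis had 0 of 28 higher and 0 lower (0 and 0 adjusted over the list alone). The median was 0.16 (camera, adjusted p = 0.297). Values were 0.09 ± 0.38 for Pck1 and -0.67 ± 0.53 for G6pc. The iron exporter Slc40a1 was lower, at -0.92 ± 0.27, and Fth1, at 0.18 ± 0.20, did not pass. Under scaling by library size alone the median of all genes moved by -0.18 and calls split into 392 higher and 1974 lower, and the gluconeogenesis median was -0.03. Against matched genes the difference was 0.31 (-0.06 to 0.42) for proximal tubule markers. With the adipocyte term Fasn (0.63) and Acaca (0.58) did not pass (edgeR's quasi-likelihood test, BH-adjusted p = 0.614 and 0.576), nor did the fatty acid synthesis list (camera, adjusted p = 0.354), Plin1 (1.11) or Cidec (-0.015). Nor did Insig1, Slco1a1 and the sex-chromosome genes, with log2 fold changes within 1.5 times. The number of genes called was 435, 996 and 1044 without WT-labelled 6 h replicates 2, 3 and 4 in turn and 805, 890, 656 and 1048 without KO-labelled 6 h replicates 1, 2, 3 and 4 in turn. Of the genes named as called only Slc17a2 and Idi1 passed without each of the 8 libraries in turn, though folds stayed within 1.5 times, and the adipocyte median was 6.87 without WT-labelled replicate 4.

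At 12 h genes of mitochondrial energy metabolism were higher in KO-labelled kidneys. Nuclear oxidative phosphorylation genes had 70 of 72 higher and 0 lower (70 and 0 adjusted over the list alone). The median log2 fold change was 0.79 (camera, adjusted p = 1.85e-18, adjusted p = 0.388 with an estimated correlation). Cytochrome c (Cycs) was higher by 0.97 ± 0.24 (log2 fold change ± SE, n = 4 per group), the complex I subunit Ndufc2 by 0.96 ± 0.18 and the ATP synthase subunit Atp5g3 by 0.95 ± 0.19. Protein genes of the mitochondrial genome had 8 of 13 higher and 1 lower (10 and 1 adjusted over the list alone). The median was 1.08 (camera, adjusted p = 2.65e-04, adjusted p = 0.247 with an estimated correlation). TCA cycle and pyruvate dehydrogenase genes had 23 of 25 higher and 0 lower (23 and 0 adjusted over the list alone). The median was 0.76 (camera, adjusted p = 7.92e-10, adjusted p = 0.247 with an estimated correlation). Both subunits of the mitochondrial pyruvate carrier, Mpc1 (1.37 ± 0.15) and Mpc2 (0.95 ± 0.19), were higher, as were Ogdhl (1.51 ± 0.53) and the succinate dehydrogenase subunit Sdhb (1.01 ± 0.16). Gluconeogenic genes had 19 of 28 higher and 0 lower (19 and 0 adjusted over the list alone). The median was 0.85 (camera, adjusted p = 5.99e-06, adjusted p = 0.247 with an estimated correlation). They included the aspartate aminotransferase Got1 (1.64 ± 0.24), ketohexokinase Khk (1.32 ± 0.24), glycerol kinase Gk (1.22 ± 0.18), Fbp1 (0.93 ± 0.26) and Pck1 (ENSMUSG00000027513, chromosome 2, 173153048 to 173159273; 1.01 ± 0.39), the rate-limiting enzyme, while G6pc stood at 1.08 ± 0.53 and did not pass. Glycolysis had 10 of 26 higher and 3 lower (10 and 3 adjusted over the list alone), where the lactate transporter Slc16a1 (1.97 ± 0.32) and Gapdh (1.12 ± 0.15) were higher and the pyruvate kinase Pklr (-1.19 ± 0.36) was lower. The list had a median of 0.38 (camera, adjusted p = 0.0149, adjusted p = 0.247 with an estimated correlation). Amino acid catabolism had 25 of 41 higher and 1 lower (27 and 1 adjusted over the list alone). The median was 0.75 (camera, adjusted p = 2.55e-07, adjusted p = 0.247 with an estimated correlation). Among them were Bhmt (2.22 ± 0.81), which remethylates homocysteine, and the agmatinase Agmat (1.93 ± 0.34). Pck1 did not pass without WT-labelled replicate 1 or 2 or KO-labelled replicate 1 or 2 (0.97, 0.69, 0.95 and 0.86), nor did Ogdhl and Bhmt without 1 library or another, Bhmt reaching 3.42 without WT-labelled replicate 1. Without WT-labelled replicate 3 Pklr (-0.73) did not pass and G6pc (1.66) did.

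Immediate early genes had 21 of 26 higher and 0 lower (21 and 0 adjusted over the list alone). The median was 1.87 (camera, adjusted p = 1.52e-08, adjusted p = 0.247 with an estimated correlation). Among them were the AP-1 subunits Fos (3.68 ± 0.52) and Fosb (3.19 ± 0.54) and the zinc finger factor Egr1 (3.35 ± 0.49). Clock genes had 12 of 19 higher and 0 lower (12 and 0 adjusted over the list alone). The median was 1.14 (camera, adjusted p = 2.65e-04, adjusted p = 0.247 with an estimated correlation). The repressors Nfil3 (2.80 ± 0.32) and Ciart (2.39 ± 0.49) were higher. The inflammation list had 13 of 41 higher and 1 lower (12 and 1 adjusted over the list alone). The median was 0.58 (camera, adjusted p = 0.0129, adjusted p = 0.669 with an estimated correlation). The neutrophil growth factor Csf3 (3.98 ± 1.07), the cytokine Il6 (3.65 ± 0.83) and the chemokine Cxcl1 (3.26 ± 0.80) were higher. Of iron genes, Fth1 was higher (0.61 ± 0.20) and Slc40a1 lower (-1.11 ± 0.28). Markers of the proximal tubule had 16 of 36 higher and 3 lower (17 and 3 adjusted over the list alone), including the phosphate transporters Slc34a1 (1.55 ± 0.25) and, in the endocrine list, Slc34a3 (2.06 ± 0.35). The markers had a median of 0.69 (camera, adjusted p = 0.002, adjusted p = 0.380 with an estimated correlation). The injury marker Havcr1, known as kidney injury molecule, was lower, at -3.03 ± 0.85, and Lcn2 stood at 0.54 ± 0.62. WT-labelled 12 h replicate 2 lay at -68.7 on the first principal component of log2 CPM, among the untreated libraries (-76.3 to -66.8). Without it Lcn2 stood at 0.15 (at 1.09 without replicate 4), and Fth1, at 0.41, did not pass. Of summed cell type markers only those of hepatocytes parted the groups, higher in every KO-labelled library (382 to 461 against 232 to 373 CPM). Endothelial markers had 0 of 15 higher and 10 lower (0 and 11 adjusted over the list alone), including the angiopoietin receptor Tek (-2.18 ± 0.40) and the diaphragm protein Plvap (-2.06 ± 0.40). Their median was -0.75 (camera, adjusted p = 0.0025, adjusted p = 0.634 with an estimated correlation).

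Among the highest log2 fold changes were 4.27 ± 0.73 for the protease inhibitor Serpina3f, 3.86 ± 0.63 for Wnt11, 3.85 ± 0.40 for Lingo4, 3.77 ± 0.59 for Rab30 and that of Fos. Among the lowest were -5.21 ± 0.76 for B3galt2, -5.08 ± 0.33 for Kctd21, -4.24 ± 0.37 for the endothelial factor Sox18, -3.82 ± 0.26 for Senp8 and -3.45 ± 0.33 for Gja5, a connexin of arteries. In all, 8631 genes passed, 3956 higher and 4675 lower, of which 1278 and 2620 by at least 2-fold. KO-labelled libraries at 12 h had 11.6 ± 0.934% of gene counts from the mitochondrial genome (SD, n = 4) against 8.0 ± 0.464% in WT-labelled ones, and their 10 highest genes took 17.3 ± 0.532% against 11.9 ± 1.04%. Log2 fold changes also ran with transcript length, from a median of 0.40 for genes under 1 kb to -0.25 for those of 4 kb or more, and oxidative phosphorylation transcripts are mostly short. With library size as the scaling the median of all genes moved by -0.51 and calls split into 1178 higher and 8781 lower. List medians moved with it to within 0.12, that of oxidative phosphorylation to 0.29 and that of glycolysis to -0.12. Against matched genes the difference was 0.21 (0.18 to 0.27) for oxidative phosphorylation, 0.52 (0.39 to 0.85) for mitochondrial genome genes, 0.16 (0.05 to 0.30) for the TCA cycle, 0.28 (0.07 to 0.48) for gluconeogenesis, 0.04 (-0.15 to 0.33) for glycolysis, 0.22 (0.03 to 0.43) for amino acid catabolism and 0.24 (0.02 to 0.48) for proximal tubule markers.

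At 20 h oxidative phosphorylation genes stood higher again in KO-labelled kidneys, with 72 of 72 higher and 0 lower (72 and 0 adjusted over the list alone). The median log2 fold change was 1.12 (camera, adjusted p = 1.04e-27, adjusted p = 0.364 with an estimated correlation). Complex I subunit Ndufa5 was higher by 1.49 ± 0.25 (log2 fold change ± SE, n = 4 per group), cytochrome oxidase subunit Cox6c by 1.36 ± 0.23 and complex III subunit Uqcr11 by 1.35 ± 0.23. TCA cycle genes had 22 of 25 higher and 0 lower (23 and 0 adjusted over the list alone). The median was 0.86 (camera, adjusted p = 9.82e-11, adjusted p = 0.248 with an estimated correlation). The pyruvate carrier genes Mpc1 (1.28 ± 0.15) and Mpc2 (1.22 ± 0.19) were among them. Gluconeogenesis had 16 of 28 higher and 1 lower (17 and 2 adjusted over the list alone). The median was 0.69 (camera, adjusted p = 5.08e-04, adjusted p = 0.335 with an estimated correlation). Of its members Khk (1.65 ± 0.24), Fbp1 (0.91 ± 0.26) and the lactate transporter Slc5a12 (1.76 ± 0.31) were higher, and Pck1 stood at 0.93 ± 0.39. Glycolysis had 16 of 26 higher and 1 lower (16 and 2 adjusted over the list alone). The median was 0.66 (camera, adjusted p = 0.0023, adjusted p = 0.247 with an estimated correlation). The lactate exporter Slc16a3 was higher (1.95 ± 0.35) and Pklr lower (-1.87 ± 0.36). Amino acid catabolism and creatine synthesis had 28 of 41 higher and 2 lower (30 and 3 adjusted over the list alone). The median was 0.82 (camera, adjusted p = 8.19e-08, adjusted p = 0.248 with an estimated correlation). Gatm, the first enzyme of creatine synthesis, was higher by 3.39 ± 0.69 and the kynurenine pathway enzyme Acmsd by 2.44 ± 0.55. Proximal tubule markers had 11 of 36 higher and 4 lower (11 and 4 adjusted over the list alone). The median was 0.41 (camera, adjusted p = 0.0213, adjusted p = 0.677 with an estimated correlation). The inositol oxygenase Miox (2.61 ± 0.32) and Slc34a1 (1.89 ± 0.26) were higher, and Havcr1 was lower, at -4.48 ± 0.89. Pck1 passed without WT-labelled replicate 1 or KO-labelled replicate 2 or 3 (1.05, 1.04 and 1.08) and stood at 0.48 without KO-labelled replicate 4, the male. The proximal tubule list did not pass without that library (0.25) or WT-labelled replicate 3 (0.27). Summed markers of hepatocytes (378 to 567 against 713 to 899.6 CPM) were lower in every KO-labelled library. Those of muscle, mesangial cells and fibroblasts were too, perhaps by scaling (mean TMM factors 0.846 against 1.113).

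Inflammatory transcripts had 24 of 41 higher and 2 lower (24 and 2 adjusted over the list alone). The median was 1.58 (camera, adjusted p = 5.08e-04, adjusted p = 0.677 with an estimated correlation). The highest log2 fold changes included 7.45 ± 1.10 for the chemokine Ccl3, 5.89 ± 0.99 for Ccl4, 5.87 ± 1.03 for Csf3, 4.50 ± 0.80 for Il6 and 4.30 ± 0.96 for Cxcl3. Neutrophil markers, which moved with them, had 8 of 14 higher and 0 lower (9 and 0 adjusted over the list alone). The median was 1.22 (camera, adjusted p = 0.0087, adjusted p = 0.677 with an estimated correlation). The lowest values included -4.89 ± 1.54 for the plasma protein Ahsg, -4.70 ± 0.31 for Kctd21, -4.68 ± 1.23 for hemopexin (Hpx), which binds free heme, -4.62 ± 1.18 for vitronectin and that of Havcr1. The immediate early list had 18 of 26 higher and 2 lower (18 and 2 adjusted over the list alone). The median was 1.46 (camera, adjusted p = 3.15e-04, adjusted p = 0.677 with an estimated correlation). Fos was higher (3.01 ± 0.50) and Egr2 lower (-2.60 ± 0.43). Cell cycle genes had 18 of 35 higher and 0 lower (18 and 0 adjusted over the list alone). The median was 0.65 (camera, adjusted p = 8.51e-04, adjusted p = 0.677 with an estimated correlation). Among them were the mitotic kinase Bub1 (2.21 ± 0.58), the proliferation marker Mki67 (1.98 ± 0.33) and the ribonucleotide reductase Rrm2 (1.97 ± 0.20). Of iron genes none of the 4 named at 0 h passed, with values of 0.24 ± 0.20 for Fth1, 0.22 ± 0.21 for Ftl1, -0.59 ± 0.27 for Slc40a1 and -0.21 ± 0.23 for Tfrc. In all, 8192 genes passed, 4134 higher and 4058 lower. Median log2 fold changes ran from 0.58 for genes under 1 kb to -0.22 for those of 4 kb or more. Library slopes on length were -0.213 to 0.013 in KO-labelled and 0.062 to 0.169 in WT-labelled libraries. Library-size scaling moved the median by -0.39 and split the calls into 1919 higher and 7201 lower. List medians moved with it to within 0.15, that of oxidative phosphorylation to 0.72 and that of proximal tubule markers to -0.002. Upper-quartile factors split the calls into 3716 higher and 4536 lower. Against matched genes the difference was 0.32 (0.29 to 0.37) for oxidative phosphorylation, 0.24 (0.11 to 0.38) for the TCA cycle, 0.22 (0.01 to 0.44) for gluconeogenesis, 0.30 (-0.03 to 0.77) for glycolysis, 0.36 (0.16 to 0.59) for amino acid catabolism and -0.16 (-0.43 to 0.39) for proximal tubule markers. Without KO-labelled replicate 3 the inflammation median was 0.61 and that of the cell cycle 0.32, Ccl3 stood at 4.63, Ccl4 at 3.46, Il6 at 2.87 and Bub1 at 1.45, and Slc40a1, at -0.95, passed. Without WT-labelled replicate 1 Hpx was at -3.08 and vitronectin at -2.91, and without KO-labelled replicate 4 the neutrophil list did not pass (0.94).

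Other genes fixed for KO against WT had these log2 fold changes ± SE (n = 4 per group) at 0, 6, 12 and 20 h. The NRF2 target Nqo1 was at -0.06 ± 0.29, 0.26 ± 0.29, 0.39 ± 0.29 and -0.06 ± 0.29, the glutathione synthesis gene Gclm at -0.54 ± 0.15, 0.40 ± 0.15, 0.23 ± 0.15 and 0.04 ± 0.15 and the fatty acid importer Cpt1a at -0.28 ± 0.26, 0.25 ± 0.26, 0.58 ± 0.27 and 0.47 ± 0.27. The proximal tubule factor Hnf4a was at -0.27 ± 0.21, 0.57 ± 0.21, -0.08 ± 0.21 and -0.42 ± 0.21 and Ppargc1a, a coactivator of mitochondrial biogenesis, at 0.06 ± 0.22, -0.43 ± 0.22, -0.65 ± 0.22 and -0.11 ± 0.22. Of these values only that of Ppargc1a at 12 h passed. At 0 and 6 h Slc34a1 was at -0.50 ± 0.25 and 0.65 ± 0.25, Havcr1 at 1.28 ± 0.83 and 2.45 ± 0.88 and Lcn2 at 0.27 ± 0.67 and -1.05 ± 0.63, and at 6 and 12 h Ftl1 was at -0.27 ± 0.21 and 0.00 ± 0.21 and Tfrc at 0.28 ± 0.23 and -0.02 ± 0.23, none of which passed. Fbp1 at 6 h (0.28 ± 0.26), and G6pc (0.39 ± 0.52) and Lcn2 (-0.73 ± 0.62) at 20 h, did not pass either. At 12 h Nqo1 (0.71), Gclm (0.41) and Cpt1a (0.78) passed without WT-labelled replicate 3, Cpt1a also without KO-labelled replicate 3 (0.69), and Ppargc1a did not pass without WT-labelled replicate 1 or 2 or KO-labelled replicate 1 (-0.52, -0.48 and -0.60). At 20 h Hnf4a passed without WT-labelled replicate 3 (-0.60) or KO-labelled replicate 4 (-0.57) and G6pc without WT-labelled replicate 1 (1.99), and Lcn2 was at -0.34 without WT-labelled replicate 3.

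The KO-to-WT comparisons at different times use different libraries. Between 12 and 20 h, 2969 genes were higher at both (901 for independent lists of these sizes) and 3260 lower at both (1045). Only Utp20 was higher at 12 h and lower at 20 h (0.84 ± 0.21 and -0.64 ± 0.21), and 13 genes the reverse. Without WT-labelled 20 h replicate 1 the 20 h value of Utp20 was -0.44 and did not pass. Between 6 and 12 h, 260 were higher at both (151) and 440 lower at both (239), and with the sex term 15 and 31. From 0 h to 12 h, 6 were higher at both (17.4) and 3 lower at both (13.6), namely Keg1, AC149090.1 and Gm15895. Another 24 were lower at 0 h and higher at 12 h (11.5) and 15 the reverse (20.6). From 0 h to 6 h, 5 were higher (3.10) and 3 lower at both (2.70). Another 26 were lower at 0 h and higher at 6 h (2) and 10 the reverse (4.10). With the sex term these counts were 1, 0, 6 and 1, and Pearson r over genes went from -0.124 to 0.191. Keg1, AC149090.1 and Gm15895 lost the 0 h call without 1 library or another, as did Gm15895 at 12 h without WT-labelled replicate 3 (-1.14). The genes named from overlaps were chosen after their values were seen.

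**Figure D2:**
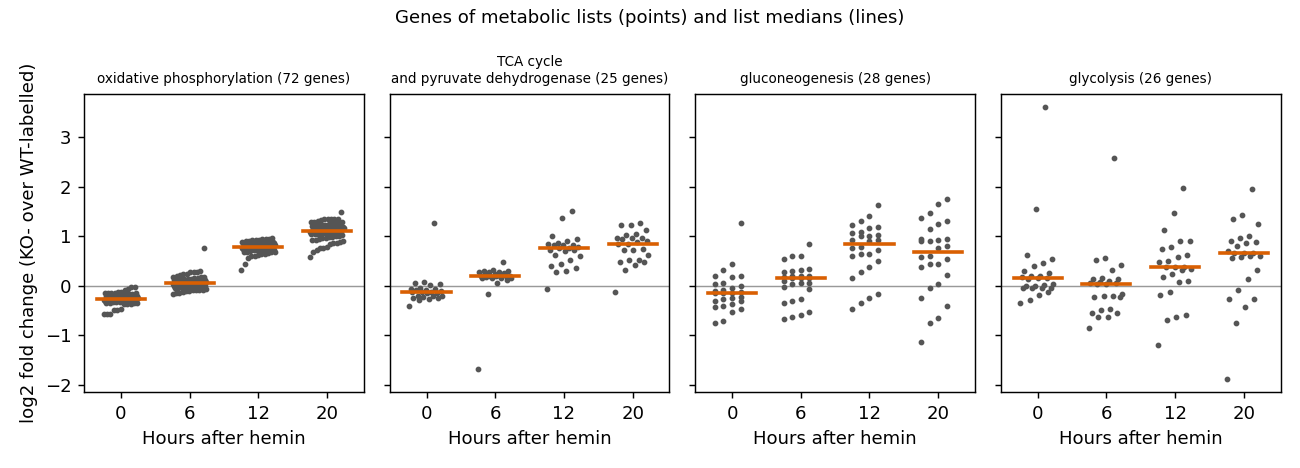
Log2 fold changes, KO-labelled against WT-labelled, of every tested gene for oxidative phosphorylation, the TCA cycle, gluconeogenesis and glycolysis at 0, 6, 12 and 20 h (points), with list medians as lines. At 20 h all 72 oxidative phosphorylation genes lie above 0, around a median of 1.12, and at 0 h their median is -0.27.

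The next comparisons follow WT-labelled kidneys after hemin, each against the untreated WT-labelled libraries. At 6 h, when the treated libraries were all female and the untreated ones all male, the acute phase gene Saa1 rose by 8.07 ± 1.31 (log2 fold change ± SE, n = 4 per group), and Saa2, at 0 in every untreated library, was at least 131-fold higher. Immediate early genes had 24 of 26 higher and 0 lower (25 and 0 adjusted over the list alone). The median was 1.87 (camera, adjusted p = 3.34e-19, adjusted p = 0.0492 with an estimated correlation). Fosl1 rose by 5.97 ± 1.29. Glucocorticoid-responsive genes had 15 of 15 higher and 0 lower (15 and 0 adjusted over the list alone). The median was 2.70 (camera, adjusted p = 4.61e-16, adjusted p = 0.0345 with an estimated correlation). Among them were the receptor-induced factor Zbtb16 (4.46 ± 0.74), the pyruvate dehydrogenase kinase Pdk4 (4.24 ± 0.80) and the cell cycle inhibitor Cdkn1a (4.78 ± 0.53). The tubular injury marker Lcn2 rose by 4.41 ± 0.73. Gluconeogenesis had 11 of 28 higher and 0 lower (12 and 1 adjusted over the list alone). The median was 0.28 (camera, adjusted p = 3.74e-04, adjusted p = 0.176 with an estimated correlation). Pck1 (2.42 ± 0.40) and G6pc (2.42 ± 0.55) rose. The largest changes included sex-chromosome genes, with Xist up by 11.84 ± 3.62 and Eif2s3y at -11.64 ± 3.64, and the transporter Slc7a13 fell by 9.03 ± 2.66. In all, 4035 genes passed, 2052 higher and 1983 lower, and 3309 with the sex term. Of the genes named, Xist, Eif2s3y and Slc7a13 did not pass with it, nor Xist and Eif2s3y without 1 library or another. Upper-quartile factors split the calls into 1985 higher and 2150 lower. In every treated library the summed markers of the proximal tubule (36652 to 39331 against 57007 to 76468 CPM) and lymphocytes (8.99 to 11.9 against 12.6 to 22.2 CPM) were lower than in every untreated one. Those of the distal convoluted tubule (1588 to 1962 against 1075 to 1531 CPM), podocytes (633 to 642 against 461 to 546 CPM), hepatocytes (478 to 808 against 286 to 458 CPM), neutrophils and the adrenal gland were higher.

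At 12 h injury genes rose in WT-labelled kidneys, with 30 of 37 higher and 0 lower (33 and 0 adjusted over the list alone). Their median was 1.51 (camera, adjusted p = 1.32e-19, adjusted p = 0.0304 with an estimated correlation). Rises were 7.28 ± 1.42 (log2 fold change ± SE, n = 4 per group) for the keratin Krt20, 7.18 ± 0.82 for Lcn2 and 6.78 ± 1.15 for the fibrinogen chain Fgb. Markers of the proximal tubule had 1 of 36 higher and 18 lower (1 and 23 adjusted over the list alone). The median was -1.08 (camera, adjusted p = 6.59e-10, adjusted p = 0.0304 with an estimated correlation). Slc34a1 fell by 1.59 ± 0.25. Targets of ATF4, a factor of amino acid and redox stress, had 24 of 33 higher and 1 lower (28 and 3 adjusted over the list alone). The median was 1.32 (camera, adjusted p = 1.26e-13, adjusted p = 0.0304 with an estimated correlation). The glutathione-degrading Chac1 rose by 5.24 ± 0.82. The highest changes included 8.53 ± 1.31 for Saa1, 8.01 ± 1.44 for Saa3, 7.65 ± 1.12 for the protease inhibitor Serpina3n, 7.54 ± 1.66 for haptoglobin, which binds free hemoglobin, and 7.49 ± 1.26 for Fosl1, and the lowest -3.60 ± 0.61 for the phosphodiesterase Pde6a and -3.06 ± 0.57 for Fancd2os. Adipocyte markers moved with the treated group, with 6 of 9 higher and 0 lower (9 and 0 adjusted over the list alone). The median was 5.34 (camera, adjusted p = 2.60e-04, adjusted p = 0.385 with an estimated correlation). They summed to 5.82 to 714 CPM there. In all, 3637 genes passed, 2047 higher and 1590 lower. Library-size scaling split the calls into 2661 higher and 1076 lower. The count was 2349 without WT-labelled 12 h replicate 4, and replicate 2 lay among the untreated libraries on the first principal component. With the adipocyte term haptoglobin (3.26) did not pass.

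At 20 h oxidative phosphorylation genes fell in WT-labelled kidneys, with 0 of 72 higher and 71 lower (0 and 72 adjusted over the list alone). The median was -0.81 (camera, adjusted p = 9.82e-22, adjusted p = 0.270 with an estimated correlation). The log2 fold changes ± SE (n = 4 per group) of the complex I subunit Ndufv3 and the ATP synthase subunit Atp5k were -1.44 ± 0.17 and -1.29 ± 0.21. TCA cycle genes had 1 of 25 higher and 17 lower (1 and 19 adjusted over the list alone). The median was -0.44 (camera, adjusted p = 2.84e-06, adjusted p = 0.270 with an estimated correlation). Mpc2 stood at -1.24 ± 0.19. Proximal tubule markers had 2 of 36 higher and 25 lower (2 and 26 adjusted over the list alone). The median was -1.10 (camera, adjusted p = 1.30e-08, adjusted p = 0.0718 with an estimated correlation). Gatm (-4.12 ± 0.72), Miox (-2.47 ± 0.32) and Slc34a1 (-2.12 ± 0.26) fell. Amino acid catabolism had 2 of 41 higher and 23 lower (4 and 26 adjusted over the list alone). The median was -0.56 (camera, adjusted p = 5.70e-06, adjusted p = 0.246 with an estimated correlation). The kynurenine enzyme Acmsd stood at -4.23 ± 0.59. Injury genes had 29 of 37 higher and 0 lower (30 and 0 adjusted over the list alone). The median was 1.93 (camera, adjusted p = 4.07e-15, adjusted p = 0.0718 with an estimated correlation). Krt20 rose by 11.45 ± 1.59, Lcn2 by 9.01 ± 0.89 and the matrix protease Mmp7, counted with the fibrosis genes, by 7.66 ± 0.96. Inflammation genes had 27 of 41 higher and 1 lower (29 and 2 adjusted over the list alone). The median was 1.75 (camera, adjusted p = 6.25e-10, adjusted p = 0.229 with an estimated correlation). Saa1 (11.51 ± 1.34) and Fosl1 (9.81 ± 1.28) were among the highest beside Krt20 and Saa2, the last at least 505-fold higher than a group at 0. Hsd3b4 (-7.25 ± 1.92), Hsd3b2 (-5.56 ± 0.81), Pde6a (-4.80 ± 0.65) and Fancd2os (-4.60 ± 0.63) were among the lowest. In all, 7124 genes passed, 3689 higher and 3435 lower. Upper-quartile factors split the calls into 3200 higher and 3919 lower, and library size alone into 4279 and 2778. Median log2 fold changes ran with transcript length, from -0.40 under 1 kb to 0.18 at 4 kb or more. At 12 and 20 h summed proximal tubule markers were lower, and neutrophil and adrenal markers higher, in every treated than in every untreated library, and at 20 h so were those of hepatocytes (713 to 899.6 against 286 to 458 CPM) and macrophages (235 to 428 against 171 to 202 CPM). Vehicle-treated or clock-matched kidneys were not analysed here, so hemin, handling and time of day are not separated in these comparisons or in those that follow.

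In KO-labelled kidneys, fatty acid oxidation genes rose 6 h after hemin, with 24 of 38 higher and 0 lower (26 and 0 adjusted over the list alone). The median was 0.77 (camera, adjusted p = 8.98e-10, adjusted p = 0.225 with an estimated correlation). The nuclear receptor Ppara, a regulator of these genes, rose by 1.88 ± 0.39 (log2 fold change ± SE, n = 4 per group). Gluconeogenesis had 16 of 28 higher and 1 lower (19 and 1 adjusted over the list alone). The median was 0.66 (camera, adjusted p = 1.48e-07, adjusted p = 0.0911 with an estimated correlation). Pck1 rose by 2.64 ± 0.41 and G6pc by 2.22 ± 0.55. Glucocorticoid-responsive genes had 13 of 15 higher and 0 lower (14 and 0 adjusted over the list alone). The median was 2.50 (camera, adjusted p = 5.92e-13, adjusted p = 0.0911 with an estimated correlation). The chaperone Fkbp5 rose by 4.10 ± 0.45. Fosl1 (6.14 ± 1.25), Eif4ebp3 (5.57 ± 0.73) and Cxcl1 (5.33 ± 0.94) rose, and Tgfb2 (-4.33 ± 0.68), Slitrk6 (-3.81 ± 0.93) and the lactate receptor Hcar1 (-3.41 ± 0.62) fell. In all, 5222 genes passed, 2369 higher and 2853 lower. Library-size scaling moved the median by -0.36 and split calls into 880 higher and 6566 lower. Relative to matched genes the difference was 0.41 (0.27 to 0.63) for fatty acid oxidation and 0.22 (0.02 to 0.42) for gluconeogenesis. Summed markers of the thick ascending limb, intercalated cells, endothelium, lymphocytes, and mesangial cells and fibroblasts were lower, and those of neutrophils higher, in every KO-labelled library at 6, 12 and 20 h than in every untreated one. Adrenal markers rose at 20 h. Mean TMM factors, not used in these sums, were 1.186 at 0 h and 0.921, 0.792 and 0.846 after hemin, so scaling may give the lower ones.

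At 12 h fatty acid oxidation had 33 of 38 higher and 0 lower (34 and 0 adjusted over the list alone). The median was 0.99 (camera, adjusted p = 7.93e-09, adjusted p = 0.231 with an estimated correlation). Oxidative phosphorylation had 67 of 72 higher and 0 lower (70 and 0 adjusted over the list alone). The median was 0.72 (camera, adjusted p = 6.79e-12, adjusted p = 0.402 with an estimated correlation). Pck1 rose by 2.66 ± 0.41 (log2 fold change ± SE, n = 4 per group). NRF2 targets had 29 of 42 higher and 2 lower (29 and 2 adjusted over the list alone). The median was 0.79 (camera, adjusted p = 1.84e-06, adjusted p = 0.209 with an estimated correlation). Slc7a11 rose by 6.02 ± 0.78. The ferritin heavy chain Fth1 rose by 1.49 ± 0.21. Fos rose by 6.18 ± 0.59, and of injury genes Lcn2 rose by 7.45 ± 0.83 and Cdkn1a by 6.53 ± 0.58. Fosl1 (10.15 ± 1.27), Cyp2b10 (8.97 ± 2.51), Cxcl2 (8.51 ± 1.37) and Saa1 (7.95 ± 1.20) were among the highest, and Slitrk6 (-7.12 ± 1.22), the apelin receptor Aplnr (-5.77 ± 0.71), B3galt2 (-5.59 ± 0.77) and Kcna1 (-5.30 ± 0.92) among the lowest. In all, 10496 genes passed, 4980 higher and 5516 lower. Median log2 fold changes ran from 0.43 for genes under 1 kb to -0.28 for 4 kb or more. The median of all genes moved by -0.58 with library size alone, which split calls into 1818 higher and 9649 lower, and by -0.13 with upper-quartile factors. The first of these took the oxidative phosphorylation median to 0.14. Relative to matched genes the difference was 0.51 (0.32 to 0.85) for fatty acid oxidation, 0.05 (0.03 to 0.07) for oxidative phosphorylation and 0.29 (0.19 to 0.40) for NRF2 targets.

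At 20 h the inflammation list rose in KO-labelled kidneys, with 35 of 41 higher and 1 lower (35 and 1 adjusted over the list alone). The median was 3.61 (camera, adjusted p = 4.65e-12, adjusted p = 0.219 with an estimated correlation). Cxcl2 rose by 11.47 ± 1.42 (log2 fold change ± SE, n = 4 per group), Csf3 by 11.25 ± 1.51 and Il6 by 9.86 ± 1.13, beside Fosl1 (10.36 ± 1.28) and Saa1 (9.75 ± 1.24). The injury gene Lcn2 rose by 8.01 ± 0.85. NRF2 targets had 27 of 42 higher and 2 lower (27 and 2 adjusted over the list alone). The median was 0.65 (camera, adjusted p = 2.96e-04, adjusted p = 0.340 with an estimated correlation). Slc7a11 rose by 7.17 ± 0.81. Oxidative phosphorylation had 53 of 72 higher and 0 lower (54 and 0 adjusted over the list alone). The median was 0.55 (camera, adjusted p = 3.34e-07, adjusted p = 0.646 with an estimated correlation). The fatty acid synthesis genes Fasn (-3.57 ± 0.84) and Acaca (-3.02 ± 0.71) fell and so did the adipocyte marker Plin1 (-6.21 ± 1.64). Slitrk6 (-9.37 ± 1.48), Sptssb (-7.19 ± 1.73), B3galt2 (-6.36 ± 0.82) and Hcar1 (-5.69 ± 0.74) fell as well. In all, 10510 genes passed, 5171 higher and 5339 lower. With library size alone the median moved by -0.49 and calls split into 2336 and 8713, and with upper-quartile factors it moved by -0.17 and calls split into 4037 higher and 6359 lower. Library size alone took the oxidative phosphorylation median to 0.05. Relative to matched genes the difference was 0.26 (0.06 to 0.38) for NRF2 targets and -0.05 (-0.08 to 0.03) for oxidative phosphorylation. With the adipocyte term Fasn (-1.31), Acaca (-1.13) and Plin1 (-1.16) did not pass, and without KO-labelled 0 h replicate 4 Fasn was at -1.88 and Acaca at -1.70.

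The interaction asks whether the change after hemin differed between the labels, as the KO-labelled change minus the WT-labelled change. Hmox1 was lower in it at all 3 times, at -2.71 ± 0.56 (log2 fold change ± SE) at 6 h, -2.69 ± 0.56 at 12 h and -2.80 ± 0.56 at 20 h, and its 0 h levels differed between the labels. At 6 h the contrast holds the male-to-female difference of that time as well, with values of 17.25 ± 4.07 for Slco1a1 and -21.24 ± 4.96 for Xist, genes near 0 in some groups. Of 1861 genes past the threshold (999 higher, 862 lower), 114 also passed with the sex term, under which 120 were called. Slco1a1 was among these, at 7.61, and Xist was not, nor did Xist pass without KO-labelled 0 h replicate 4 (-11.35). Library-size scaling moved the median by -0.35 and split calls into 510 and 3032, and upper-quartile factors into 918 higher and 998 lower. The count was 1239 without WT-labelled 0 h replicate 2, 1215 without KO-labelled 0 h replicate 3, 1123 without WT-labelled 6 h replicate 2 and 1144 without KO-labelled 6 h replicate 3.

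At 12 h oxidative phosphorylation genes were higher in the interaction, with 70 of 72 higher and 0 lower (72 and 0 adjusted over the list alone). The median was 1.03 (camera, adjusted p = 4.05e-23, adjusted p = 0.340 with an estimated correlation). Ndufa13 stood at 1.51 ± 0.31. Markers of the proximal tubule had 16 of 36 higher and 1 lower (17 and 2 adjusted over the list alone). The median was 1.09 (camera, adjusted p = 5.60e-05, adjusted p = 0.271 with an estimated correlation). Adipocyte markers had 0 of 9 higher and 3 lower (0 and 8 adjusted over the list alone). The median was -5.56 (camera, adjusted p = 0.0173, adjusted p = 0.595 with an estimated correlation). Adrb3 (-8.29 ± 1.84) and Plin1 (-7.09 ± 2.04) were lower, as was Slitrk6 (-6.40 ± 1.48). Angptl7 (5.36 ± 0.88) and Wnt11 (4.69 ± 0.84) were among the highest. In all, 6814 genes passed, 2915 higher and 3899 lower. The median of all genes moved by -0.67 with library size alone, with 733 higher and 8774 lower, and by -0.10 with upper-quartile factors. Under library size alone the adipocyte list did not pass (camera, adjusted p = 0.345), and with the adipocyte term Adrb3 (-1.88) and Plin1 (-0.51) did not. Without WT-labelled 12 h replicate 2 Slitrk6 was at -4.25. Set against matched genes the difference was 0.36 (0.30 to 0.43) for oxidative phosphorylation and 0.42 (0.19 to 0.61) for proximal tubule markers.

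At 20 h oxidative phosphorylation had 72 of 72 higher and 0 lower (72 and 0 adjusted over the list alone) in the interaction. The median was 1.39 (camera, adjusted p = 8.06e-34, adjusted p = 0.224 with an estimated correlation). Ndufa1 stood at 1.80 ± 0.31. Amino acid catabolism had 27 of 41 higher and 2 lower (27 and 2 adjusted over the list alone). The median was 0.90 (camera, adjusted p = 4.17e-08, adjusted p = 0.186 with an estimated correlation). Gatm stood at 3.15 ± 0.91. Inflammation genes had 11 of 41 higher and 1 lower (11 and 1 adjusted over the list alone). The median was 1.21, or 1.29 with members at 0 set to the floor (camera, adjusted p = 0.0136, adjusted p = 0.856 with an estimated correlation). Among them were Ccl3 (7.26 ± 1.49) and Ccl4 (6.64 ± 1.32). Plin1 (-7.89 ± 2.18), the acute phase gene Orm1 (-6.99 ± 1.68) and Adrb3 (-6.42 ± 2.18) were lower. Adipocyte markers had 0 of 9 higher and 4 lower (0 and 4 adjusted over the list alone). The median was -5.09 (camera, adjusted p = 0.015, adjusted p = 0.817 with an estimated correlation). In all, 6179 genes passed, 2993 higher and 3186 lower. Library-size scaling moved the median by -0.56, with 939 higher and 7097 lower. Under it the adipocyte list did not pass (camera, adjusted p = 0.270). Set against matched genes the difference was 0.50 (0.42 to 0.56) for oxidative phosphorylation and 0.31 (-0.02 to 0.62) for amino acid catabolism. Plin1 (-1.30), Orm1 (-3.13) and Adrb3 (-0.50) did not pass with the adipocyte term. Without KO-labelled 20 h replicate 3 the inflammation list did not pass (0.39) and Ccl3 was at 4.45 and Ccl4 at 4.22, and without WT-labelled 20 h replicate 3 neither the adipocyte list (-4.22) nor Adrb3 (-5.96) passed.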

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

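Of the tests below, those of exchanged labels, of counts from a deleted allele, of genotype at 6 h and of the scaling factors were chosen after the result was seen. Hmox1, which the KO label says is deleted, was 2.56 (mean log2 CPM, n = 4 per group) higher in KO-labelled than in WT-labelled kidneys at 0 h, and the groups overlapped after hemin. Among male libraries alone the log2 fold change at 0 h was 2.98 and passed, which argues against sex as the cause. Exchanged labels at 0 h stay open. Gm26917, higher under the KO label by 2.39 ± 0.27 at 0 h and at each later time, runs against them. It was chosen after its values were seen. Counts from a deleted allele or from cells without the deletion also stay open: the lowest KO-labelled library held 75.2 CPM, and counts are summed over the whole gene.

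At 6 h the KO-labelled libraries were all male and the WT-labelled all female. Of 1600 genes called then that were also tested without the 6 h libraries, 1394 (87.1%) had the sign of the male-minus-female effect fitted without them, against 68.3% of all genes. Of 512 that were also called for sex there, 510 had that sign, so the sex of the libraries is a candidate explanation for most of these calls. With a sex term 81 genes passed, and for these genotype and sex cannot be told apart without taking the effect of sex to be alike at all times.

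Nuclear oxidative phosphorylation genes were higher in KO-labelled kidneys at 12 and 20 h. At 12 h the median was 0.75 among male and 0.82 among female libraries, which argues against sex. With library size alone the median was 0.29 at 12 h and 0.72 at 20 h, so the scaling factors stay open for part of its size. Against genes matched on transcript length, GC content and level, the median of 0.79 at 12 h became a difference of 0.21 (95% bootstrap interval 0.18 to 0.27), and the 1.12 at 20 h became 0.32 (0.29 to 0.37). These features are thus a candidate explanation for part of the shift, and the rest, the deletion included, stays open as untested, since Hmox1 does not follow the labels.

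The libraries of each comparison of 2 groups were split in all 35 ways and refitted alone with edgeR's quasi-likelihood test. In each only the real split gave as many genes, 1 in 35, so chance is not excluded. The genes called by the real split and the highest other were 494 against 40 for KO against WT at 0 h, 4680 against 0 at 6 h, 6143 against 195 at 12 h and 5641 against 2 at 20 h. For WT-labelled kidneys against 0 h they were 4883 against 0 at 6 h, 1377 against 1 at 12 h and 5115 against 0 at 20 h, and for KO-labelled ones 8061 against 0, 10662 against 0 and 9403 against 24. At an unadjusted p under 0.05 the other splits in the comparisons with 0 gave at most 1846, 2849, 3474, 2126 and 1142 genes in that order, and DESeq2 was not run on splits. For KO against WT at 6 h and for WT-labelled kidneys at 6 h the split by sex is the real split, so sex is not excluded there, and the 195 and the 24 are from splits by sex. For the interactions, 1 of 100 draws of labels within times, the real one, gave as many genes: 4323 against 2197 at 6 h, 6124 against 4662 at 12 h and 5314 against 4112 at 20 h. In the highest other draws all 8 libraries after hemin kept their labels (or all exchanged them), and of the 8 at 0 h 4, 6 and 4 did.

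Tests of the difference between labels in the change after hemin called 1861 genes at 6 h, 6814 at 12 h and 6179 at 20 h, with Hmox1 at -2.71, -2.69 and -2.80. The log2 values named by rule at 6 h were Slco1a1 (17.25), Cyp2j13 (11.49), Slc7a13 (10.87), Mpped1 (10.85) and Acsm3 (10.07) above 0 and Xist (-21.24), Ugt1a2 (-16.51), Myh1 (-11.89), Slc17a2 (-8.48) and Igf2 (-7.87) below, of which only Slco1a1, Ugt1a2 and Slc17a2 passed with the sex term. At 12 h they were Angptl7 (5.36), Pde6a (4.78), Wnt11 (4.69), Armc12 (4.63) and Prkag3 (4.22) above 0 and Adrb3 (-8.29), B3galt2 (-7.59), Kcna1 (-7.40), Plin1 (-7.09) and Slitrk6 (-6.40) below. At 20 h they were Ccl3 (7.26), Ccl4 (6.64), Pde6a (5.49), Acod1 (4.61) and Armc12 (4.53) above 0 and Plin1 (-7.89), Ucp1 (-7.80), Orm1 (-6.99), Ahsg (-6.62) and Adrb3 (-6.42) below. Without 1 library or another Slc7a13, Xist and Myh1 at 6 h and Acod1, Ucp1, Ahsg and Adrb3 at 20 h did not pass. Values moved by over 1.5 times without KO-labelled 0 h replicate 4 for Xist (-11.35), Myh1 (-6.72) and Ucp1 (-4.94), without KO-labelled 20 h replicate 3 for Ccl3 (4.45), Ccl4 (4.22) and Acod1 (1.38) and without WT-labelled 12 h replicate 2 for Slitrk6 (-4.25).

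In 16 of 168 pairs of group and measure, 1 library lay so far from the other 3 that its gap, as a share of the group's range, passed Dixon's critical value. Chance does so in about 1 in 20 groups (8.4 expected). In WT-labelled 20 h replicate 2 the shares were 0.870 for Fth1, 0.836 for Ftl1, 0.849 for Nqo1 and 0.941 for the part of counts in the 10 highest genes. In KO-labelled 0 h replicate 4, the female of its group, they were 0.890 for Slc40a1 and 0.946 for Pck1, and in replicate 2 0.904 for Ftl1 and 0.843 for Hnf4a. In KO-labelled 20 h replicate 4, the male of its group, they were 0.893 for Pck1 and 0.851 for Lcn2. The others were 0.850 for Fth1 in WT-labelled 0 h replicate 1, 0.957 for G6pc in WT-labelled 20 h replicate 1 and 0.881 for Fbp1 in WT-labelled 6 h replicate 2. Summed adipocyte markers gave 0.848 in WT-labelled 0 h replicate 4, 0.979 in WT-labelled 6 h replicate 4 and 0.887 in KO-labelled 20 h replicate 2.

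Reads not aligned, which enter no test, took 1.31% of the total in KO-labelled libraries at 12 h and 1.46% at 20 h (means, n = 4), every library lying above every untreated WT-labelled one.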

How the results depend on the processing

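The sex term, the adipocyte term, library-size scaling and the fits of male or female libraries alone were chosen after seeing the data, and the cause of the shifts below was not tested unless a setting's own construction gives it. RLE and upper-quartile factors and a minimum count of 50 left all 13 counts of genes called within 1.5 times, and pseudocounts of 0.1 and 1 CPM left each Hmox1 difference per library on its side of the threshold. KO against WT at 0 h, with 133 genes, gave 72 with no filter, 467 with DESeq2, 494 with only the compared groups, 234 with the sex term, 25 with the adipocyte term and 551 among male libraries. At 6 h, with 1624, it gave 984 with no filter, 4680 with only the compared groups, 81 with the sex term and 1070 with the adipocyte term. Among male libraries, which are fewer, counts were 5326 at 12 h (8631) and 3633 at 20 h (8192). WT-labelled kidneys at 12 h (3637) gave 1377 with only the compared groups, 1627 with the adipocyte term and 6018 among males. KO-labelled kidneys gave 8061 at 6 h with only the compared groups (5222), 6895 at 12 h among females (10496) and 6304 at 20 h among males (10510). The interaction at 6 h (1861) gave 4323 with only the compared groups, 120 with the sex term and 3542 with library size alone. With an estimated correlation 0 lists passed in 11 comparisons (KO against WT, KO-labelled kidneys after hemin and the interaction at all times, and WT-labelled kidneys at 20 h), 3 in WT-labelled kidneys at 6 h and 5 at 12 h, where the preset correlation called 18 and 25, and from 16 to 31 in the others. At an unadjusted p under 0.05 camera gave 3 to 11 lists in these 11, and no other tool was run on lists. Genes called at both 6 and 12 h numbered 15 higher and 31 lower with the sex term (from 260 and 440), and those at both 0 and 12 h 41 and 17 with DESeq2 (from 6 and 3) and 15 and 6 with the sex term. Reversals came with the adipocyte term, which removes the markers it is made of: the adipocyte list median went to -0.16 for KO against WT at 0 h, -0.55 for WT-labelled kidneys at 12 h, and 1.06 and 1.12 for the interaction at 12 and 20 h, Cidec at 6 h to -0.015 and Ucp1 in the interaction at 20 h to 1.15.

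Leaving out 1 library in turn gave 28 (without KO-labelled 0 h replicate 3) to 145 (without KO-labelled 0 h replicate 2) genes for KO against WT at 0 h, 435 (without WT-labelled 6 h replicate 2) to 1118 (without WT-labelled 6 h replicate 1) at 6 h, 2349 (without WT-labelled 12 h replicate 4) to 5079 (without WT-labelled 12 h replicate 2) for WT-labelled kidneys at 12 h and 1123 (without WT-labelled 6 h replicate 2) to 1782 (without WT-labelled 0 h replicate 4) for the interaction at 6 h. Every other count stayed within 1.5 times. Of 295 values of named genes, 46 lost the call in at least 1 such fit and 9 gained one, and of 62 list results 5 lost and 2 gained, and 0 of those called changed sign. Among named genes the call was lost in 2 with RLE factors, 1 with upper-quartile factors, 26 with no filter, 10 with only the compared groups, 30 with the sex term, 32 with the adipocyte term and 8 with library size alone. A minimum count of 50 left 4 of them untested, DESeq2 0 and only the compared groups 4. Depth limits genes near the floor of 3 counts. Folds are given as bounds only against a group at 0, not for Xist or Eif2s3y.

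With the replicate number as a block the counts were 94, 1455, 8515 and 8094 for KO against WT at 0, 6, 12 and 20 h, 3937, 3551 and 6966 for WT-labelled and 5018, 10430 and 10378 for KO-labelled kidneys at 6, 12 and 20 h, and 1717, 6695 and 6012 for the interactions, all within 1.5 times. Correlations of same-numbered libraries' deviations from their group means ranged from -0.490 to 0.442, and in 0 of 10 comparisons were all of them over 0.1, so the numbers do not pair the libraries; from 0 to 3 of 4 correlated best with their own number. The block ended the call of 10 named genes and began that of 1, and it ended the call of 0 lists and began that of 1.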

Other observations

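The tests of AU-rich messages and of zinc finger genes were chosen after the result was seen. At 12 h NRF2 targets, which answer oxidative stress, had 17 of 42 higher and 1 lower (17 and 1 adjusted over the list alone) in KO-labelled against WT-labelled kidneys, with a median of 0.50 (camera, adjusted p = 0.0028, adjusted p = 0.435 with an estimated correlation), and the cystine transporter Slc7a11 stood at 2.50 ± 0.63 (log2 fold change ± SE, n = 4 per group) and Gsta1 at 2.44 ± 0.59. Against matched genes the list's difference was -0.06 (-0.20 to 0.19). Autophagy and lysosome genes had 17 of 31 higher and 1 lower (17 and 1 adjusted over the list alone), with a median of 0.37 (camera, adjusted p = 2.76e-04, adjusted p = 0.374 with an estimated correlation) and Ulk1 at 1.15 ± 0.20. Their matched difference was 0.03 (-0.03 to 0.19), and their median 0.55 without WT-labelled 12 h replicate 3. Macrophage and monocyte markers had 1 of 17 higher and 9 lower (1 and 10 adjusted over the list alone), with a median of -0.99 (camera, adjusted p = 0.0962), and Cx3cr1 was lower, at -3.12 ± 0.51. They passed without WT-labelled (-1.20) or KO-labelled (-1.02) replicate 3, and their median was -0.50 without WT-labelled replicate 2.

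A hypothesis for the genes lower in KO-labelled kidneys at 12 h was that short-lived messages, marked by AU-rich pentamers in the 3' UTR, fell most. Genes with 3 or more ATTTA pentamers in a 3' UTR of 500 to 1500 nt lay 0.062 (log2, 95% bootstrap interval 0.008 to 0.113) from genes with none of like length and level. They lay above, which argues against it in these libraries. The length range was set after a first run over all lengths had given 0.026 (0.006 to 0.056).

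A second hypothesis is that zinc finger transcription factor genes fell as a family. Of 425 tested, 48 were higher and 231 lower in KO-labelled kidneys at 12 h, and 44 and 227 at 20 h. The family lay -0.26 (-0.35 to -0.15) from genes matched on length, GC content and level at 12 h and -0.31 (-0.40 to -0.20) at 20 h, past the bound for the hypothesis. The same values raised the hypothesis and tested it, so it may hold for these libraries alone, and the family's median was -1.09 with library size alone against -0.59 with TMM factors.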
